A study of Mus musculus with 10 samples.

How the data were processed

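The study compared colon tissue of C57BL/6 mice in 5 groups with 2 RNA-seq libraries each, 10 libraries in all. Total RNA was made into libraries with the Illumina TruSeq RNA kit (version 2 of its preparation protocol) and sequenced on an Illumina NextSeq instrument, per the labels' protocols and the series' design text. Groups and replicate numbers (0 and 1) were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical in part.

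The deposited table holds FPKM values (fragment numbers scaled by transcript length and by the mapped fragments of the library) per RefSeq transcript, with a column for each library. The submitters' processing notes name bcl2fastq 2.17.1.14, TopHat2 2.0.9, Bowtie2 2.1.0.0 and Cuffdiff, whose version is not given in the sources used here, and the mouse genome builds mm10 and GRCm38. They give no role or order for these tools. Cuffdiff is a program that divides the fragments of a gene among its transcripts by a model before it reports FPKM, so the deposited values are estimates rather than counts. How the authors treated duplicates, multi-mapping fragments and strand is not given in the sources used here.

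The table had 30073 transcript rows. Gene names came from a RefSeq gene table of GRCm38.p6, which matched 29443 transcripts, and from GENCODE names for a further 155. The remaining 475 transcripts stayed as rows of their own under their identifiers. FPKM values were summed over the transcripts of a gene, which gave 23492 rows, of which 4384 were listed at 0 in all libraries. Of the transcripts, 524 carried a copy suffix on their identifier, and those with a gene name were summed with the others of their gene. Rows with at least 1 FPKM in at least 2 libraries were tested, 14061 in all, of which 188 had no gene name.

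Total read numbers are unknown, because FPKM removes them. The smallest steps between low values gave relative depths per library between 1.0 in Control replicate 0 and 1.35 in ASA+CUR replicate 0. These are rough, since 20.0% to 25.9% of the gene ratios behind them lay within 0.05 (log2) of their mode. No count was recovered, and no count test or counting interval was used. A value of 0 can be a failed estimate of the authors' model, so such genes are described as listed at 0 and get no fold.

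Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and all 10 libraries in 1 fit (5 residual degrees of freedom and 2.96 prior degrees of freedom). A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment within a comparison, two-sided, at a threshold of 0.05. Errors of FPKM values are standard deviations over the 2 libraries of a group, and errors of log2 differences are limma's standard errors. The planned comparisons were Model against Control, each of the 3 treated groups against Model, and ASA+CUR against ASA and against CUR. The 3 treated groups were also set against Control, a comparison added after the data were seen.

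Gene lists for pathways, cell types and controls, 35 in all, were written before the data were examined, and the 33 with at least 5 tested members were tested. The main list test was camera with a preset correlation of 0.01 between genes, which compares a list with all other genes. The same test with a correlation estimated from the libraries, and fry, which asks whether the genes of a list move on balance in a single direction, were run beside it. Adjusted p-values of lists are over the 33 lists of a comparison. A gene count "adjusted over the list alone" applies the Benjamini-Hochberg adjustment to the members of that list.

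Genes named in the text follow a rule written before the data were examined. They are the 10 highest and 10 lowest log2 changes among genes past the threshold whose libraries do not overlap between groups, up to 4 members past the threshold of each list by smallest p, the fixed genes Ptgs1, Ptgs2, Il6, Tnf, Nos2, Nqo1, Hmox1 and Axin2 in comparisons with Model, and the 6 smallest p-values where fewer than 6 genes passed. For the reversal results the rule adds the 10 genes with the largest Model change. List members named in the comparisons among AOM/DSS groups, and the genes of colon position and squamous epithelium, were chosen after their values were seen.

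Comparisons that share libraries share their chance values. Unchanged groups were therefore simulated 100 times, and the simulated value stands beside the observed value. For comparisons with Model the treated groups were set equal to Model. For comparisons with Control all groups, Model included, were set equal to Control. Every library was redrawn from the fitted spread, each gene independently, so shifts that many genes of a library share are left out. The steps were tested on simulated data with 200 changed genes among 14061, in 5 draws. The changed genes were drawn only from those with higher values in the reference group, and genes varied independently. Recovery of low genes was not tested. For Model against Control, 49.6% of genes changed by 2-fold and 94.6% of genes changed by 4-fold were recovered, and 6.85% of the calls were false. For ASA+CUR against Model, 40% and 90.2% were recovered.

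The alternatives were other pseudocounts (0.1 and 5), no filter and a filter of 5 FPKM, single transcripts, quantile and median-of-ratios scaling, other variance models, only the groups compared, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were Hoxd13 as a covariate, the removal of small RNA features, and the removal of ASA replicate 0 and ASA+CUR replicate 0. For the explanations weighed at the end, means of a list per library were given 95% t intervals in the fit of all groups, also chosen after. Names and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.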

Results

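RNA-seq was used to profile mouse colon after azoxymethane (AOM), a colon carcinogen, and dextran sulfate sodium (DSS), a detergent-like polymer that injures the colon lining, and to ask what dietary aspirin (ASA), curcumin (CUR) or both change in that tissue. Control mice received saline and the AIN-93M diet. Model mice received AOM at 10 mg/kg at an age of 6 weeks, DSS at 1.2% in the drinking water for 7 days, and the same diet. The ASA, CUR and ASA+CUR groups received AOM and DSS with a diet holding 0.02% ASA, 2% CUR, or 0.01% ASA with 1% CUR. The combination therefore held each agent at a lower dose than its own group did. The labels name the Control tissue as colon and the tissue of the 4 AOM/DSS groups as tumour, while the protocol describes a piece frozen after palpable tumours had been taken out. How much tumour the pieces held is not given in the sources used here.

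Each group had 2 libraries. The sums of FPKM lay between 515959 in ASA+CUR replicate 1 and 720895 in Control replicate 0, and 12781 to 13283 genes per library reached 1 FPKM. Mptx1, a mucosal pentraxin, made up 5.46% of all FPKM in Control replicate 0, and the ribosomal protein share ran from 14.1% in ASA+CUR replicate 1 to 18.2% in CUR replicate 0. Across genes, log2 values of the replicates correlated at 0.986 in Control, 0.964 in Model, 0.954 in ASA, 0.947 in CUR and 0.977 in ASA+CUR, and genes are not independent replicates. ASA replicate 0 correlated with ASA+CUR replicate 0 at 0.986, above its correlation with ASA replicate 1. The first principal component, with 54.6% of the variance, parted the Control libraries (85.4 each) from the 8 AOM/DSS libraries (between -40.66 and -9.04). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above 3 FPKM in all 10 libraries, and none of the 4 passed the test in Model against Control.

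**Figure D1:**
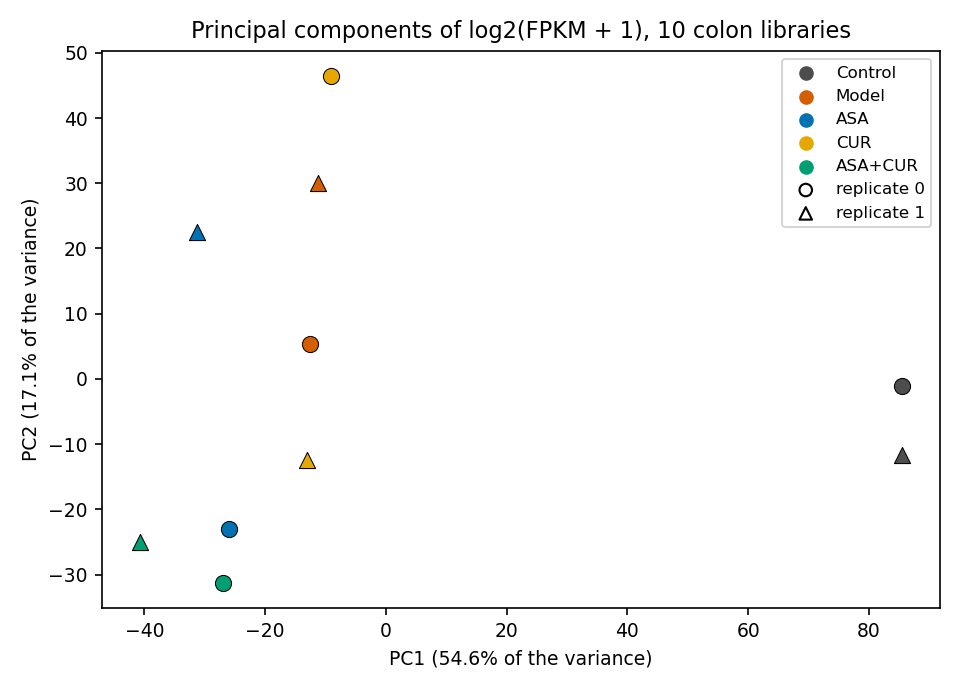
Principal components of log2(FPKM + 1) over the tested genes, with PC1 on the x axis, PC2 on the y axis and a point for each of the 10 libraries, coloured by group and shaped by replicate number. The Control libraries sit at 85.4 on PC1 and all AOM/DSS libraries below 0, while the replicates of ASA and of CUR lie on opposite sides of 0 on PC2.

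Model against Control asks what AOM and DSS changed. Lyz1 and 7 alpha-defensin genes were among the 10 genes named for the highest log2 changes. Lyz1, a lysozyme gene (chromosome 10, 117287795 to 117292868, GRCm38), rose from 6.86 ± 0.535 FPKM in Control to 2253 ± 717 in Model (SD, n = 2, log2 change 8.13 ± 0.28 SE, adjusted p = 1.84e-05). The alpha-defensins Defa24, Defa30, Defa20, Defa22, Defa5, Defa32 and Defa21 were listed at 0 in both Control libraries and reached 107 and 160.0 FPKM (Defa21) to 1650.1 and 2048 FPKM (Defa24) in the Model libraries, with adjusted p from 0.000649 to 0.00644. They are near-identical copies on chromosome 8, so the split of reads among them is uncertain. Mt4, a metallothionein gene, was also listed at 0 in Control and had 103 and 143 FPKM in the Model libraries (adjusted p = 0.00202).

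Mptx1 fell the furthest among the genes named by the rule for the lowest log2 changes. It had 39340.5 and 5012 FPKM in the Control libraries against 112 and 1.47 in the Model libraries (log2 change -9.72 ± 2.29, adjusted p = 0.0271). Car4, a carbonic anhydrase, fell from 682 ± 35.7 to 41.8 ± 39.5 FPKM and Aqp8, a water channel, from 342 ± 39.4 to 18.7 ± 15.5 (adjusted p = 0.00605 and 0.00339). Sycn, Tgm3, Retnla, the hormone genes Sst and Insl5, and Cfd, a complement protease made by fat cells, fell by 4.13 to 5.25 on the log2 scale. Snord22, a small nucleolar RNA, was listed at 0 in both Model libraries and at 92.2 and 39.8 FPKM in the Control libraries.

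Targets of Wnt signalling rose together. Of 24 tested, 20 rose and none fell, 22 rose when adjusted over the list alone, and the median log2 change was 2.23 (camera adjusted p = 1.06e-17, adjusted p = 0.0664 with an estimated correlation). Notum, a secreted Wnt inhibitor, rose from 0.473 ± 0.204 to 118 ± 26.3 FPKM, Wif1, another secreted inhibitor, from 1.21 ± 0.316 to 202 ± 58.8, and Nkd1 from 7.58 ± 1.82 to 103 ± 4.41. Axin2, a standard readout of the pathway, rose from 13.5 ± 0.605 to 67.8 ± 9.28 FPKM (log2 change 2.24 ± 0.31, adjusted p = 0.0038). Matrix metalloproteinases and their inhibitors rose in 12 of 17 members and fell in none (13 rose when adjusted over the list alone, median 2.05, camera adjusted p = 6.25e-11, adjusted p = 0.0664 with an estimated correlation). Mmp7, which is in both lists, rose from 1.13 ± 0.444 to 439 ± 50.6 FPKM and Mmp13 from 1.02 ± 0.262 to 41.6 ± 12.8.

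Genes of inflammation and of immune cells rose. Cytokines and chemokines rose in 13 of 25 members (19 when adjusted over the list alone, median 1.75, camera adjusted p = 2.19e-08, adjusted p = 0.0664 with an estimated correlation), among them Il1b from 1.47 ± 0.422 to 28.6 ± 15.1 FPKM, Tnf from 0.379 ± 0.0575 to 4.58 ± 0.760, Cxcl1 and Cxcl5. Neutrophil genes rose in 7 of 12 (8 when adjusted over the list alone, camera adjusted p = 1.8e-06, adjusted p = 0.228 with an estimated correlation), led by S100a8, at 0.189 ± 0.267 FPKM in Control and 62.1 ± 25.5 in Model, and S100a9. Macrophage and dendritic cell genes rose in 9 of 20 (15 when adjusted over the list alone, median 1.46 and 0.96 without Model replicate 1, camera adjusted p = 1.32e-07, adjusted p = 0.273 with an estimated correlation), with Arg1 from 0.664 ± 0.209 to 55.3 ± 30.1 FPKM and Spp1 from 0.466 ± 0.105 to 41.9 ± 29.7. NF-kB targets rose in 7 of 20 (10 when adjusted over the list alone, median 0.76, camera adjusted p = 0.000622, adjusted p = 0.0773 with an estimated correlation), among them Tnfaip2, Icam1, Nfkbie and Nos2.

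Interferon response genes rose in 4 of 28 members, also when adjusted over the list alone (median 1.16, camera adjusted p = 7.2e-06, adjusted p = 0.274 with an estimated correlation). Irgm2, Usp18 and Ifit2 were among these, and Usp18 rose from 1.45 ± 0.259 to 20.3 ± 0.266 FPKM. T and NK cell genes rose in 4 of 16 (12 when adjusted over the list alone, median 1.28 and 0.63 without Model replicate 1, camera adjusted p = 1.35e-05, adjusted p = 0.353 with an estimated correlation), namely Gzmb, Zap70, Foxp3 and Cd2. Of 13 mast cell genes, the proteases Tpsb2 and Cma1 rose and Kit, a receptor that pacemaker cells of the gut wall also carry, fell (9 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.00466, adjusted p = 0.406 with an estimated correlation). The mast cell list, with a median of 1.65, did not pass without Control replicate 1 (adjusted p = 0.0744) and had a median of 2.69 without Control replicate 0. None of 14 B and plasma cell genes passed, also when adjusted over the list alone (camera adjusted p = 0.132), and that list passed without Model replicate 0 (adjusted p = 0.00109). Of 22 genes of antimicrobial and mucosal defence, 8 rose and 4 fell (10 and 5 when adjusted over the list alone, median 2.48, camera adjusted p = 0.00884, adjusted p = 0.271 with an estimated correlation). Without Model replicate 0 the median of that list was 1.04 and it did not pass (adjusted p = 0.059). Lyz1, Pla2g2a, S100a8 and Lcn2 were among those that rose, and Saa1, Saa2, Retnla and Pigr, the receptor that carries IgA across the epithelium, were those that fell.

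Genes of the muscle wall and its nerves fell. Of 20 smooth muscle genes, 19 fell and none rose, and 20 fell when adjusted over the list alone (median -2.54, camera adjusted p = 1.06e-17, adjusted p = 0.145 with an estimated correlation). Des, an intermediate filament of muscle, went from 1151 ± 425 FPKM in Control to 75.8 ± 10.6 in Model, Cnn1 from 783 ± 255 to 47.3 ± 0.119, and Tpm2 from 333 ± 117 to 34.0 ± 3.27. Enteric neuron and glia genes fell in 14 of 15, also when adjusted over the list alone (median -2.04, camera adjusted p = 1.18e-13), and this was the list whose call held with an estimated correlation (adjusted p = 0.0232). Prph, a neuronal filament, fell from 17.8 ± 0.121 to 0.877 ± 0.195 FPKM and Snap25, a synaptic protein, from 14.5 and 13.9 FPKM in the Control libraries to 0.802 ± 0.325. Adipocyte genes fell in 6 of 10, also when adjusted over the list alone (median -1.99 and -0.84 without Control replicate 1, camera adjusted p = 1.12e-06, adjusted p = 0.0515 with an estimated correlation), among them Adipoq and Retn. Fibroblast and matrix genes rose in 9 of 21 and fell in none (11 rose when adjusted over the list alone, median 0.82, camera adjusted p = 0.00146, adjusted p = 0.466 with an estimated correlation), with Col1a1 from 49.2 ± 5.79 to 158 ± 63.0 FPKM. Among 15 endothelial genes, Prox1, which is also in the Wnt list, and Cdh5 rose, also when adjusted over the list alone (median 0.72, camera adjusted p = 0.00489, adjusted p = 0.466 with an estimated correlation). Neither the fibroblast nor the endothelial list passed without Model replicate 1 (medians 0.51 and 0.04, adjusted p = 0.0896 and 0.525), and the endothelial median was 1.41 without Model replicate 0.

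**Figure D2:**
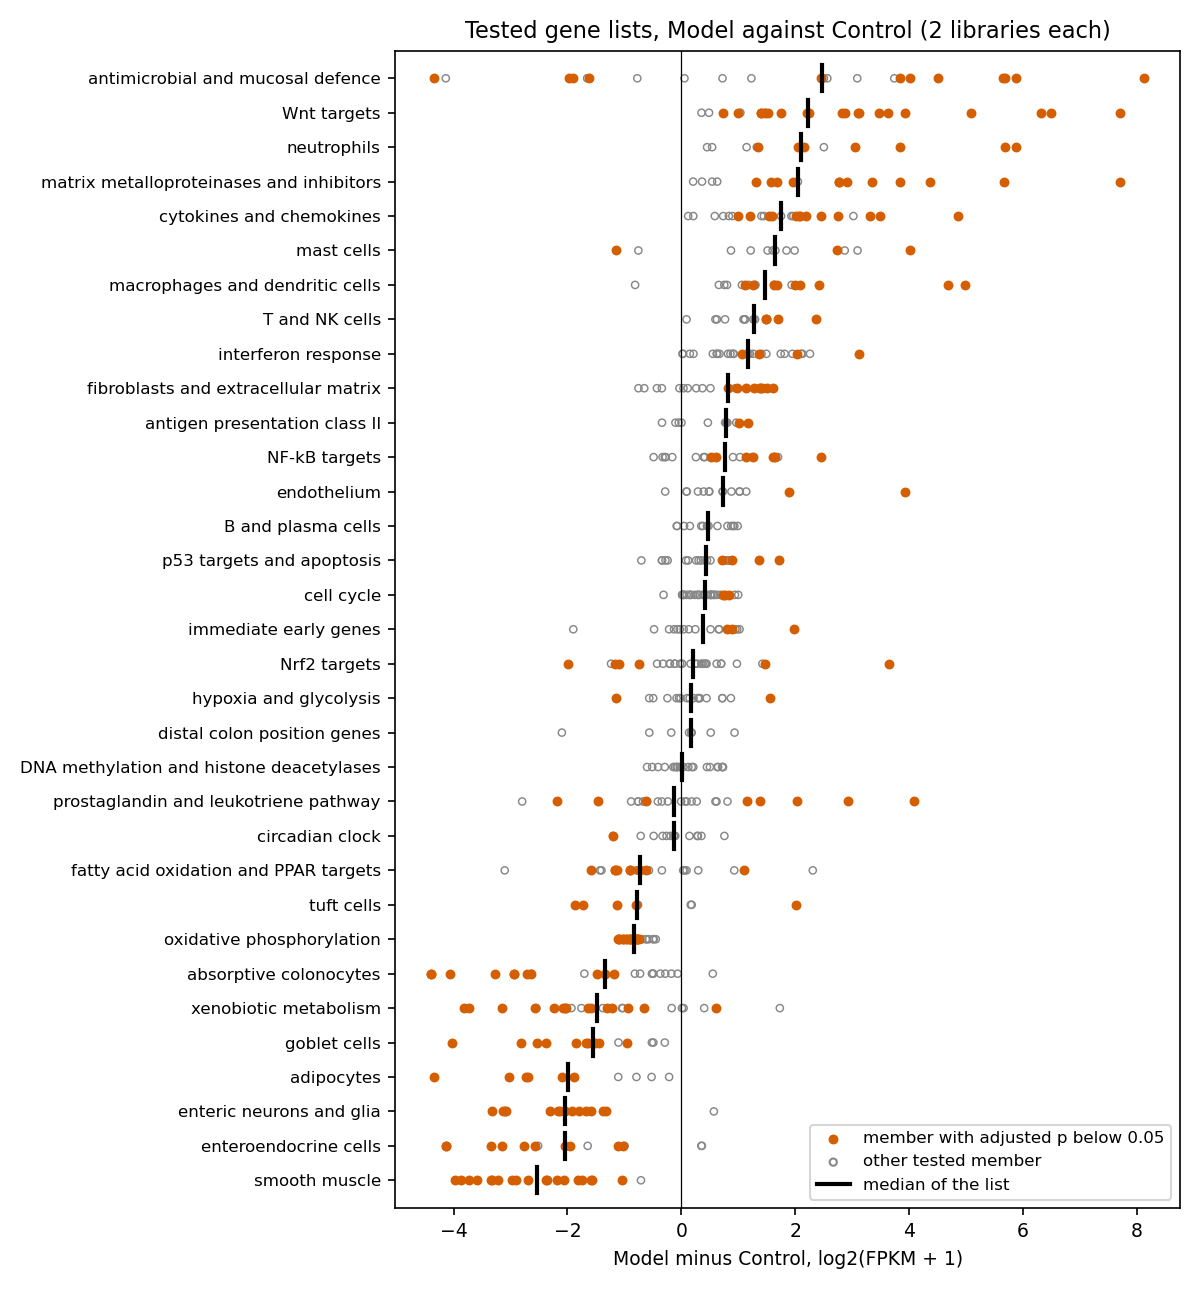
Log2 differences of Model minus Control on the log2(FPKM + 1) scale (x axis) for the tested members of 33 gene lists (y axis), with filled points for members of adjusted p below 0.05, open points for the others and a bar at the median of each list. Medians run from -2.54 for smooth muscle to 2.48 for antimicrobial and mucosal defence (1.04 without Model replicate 0), and the Wnt targets lie at 2.23.

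Genes of differentiated epithelium fell. Goblet cell genes fell in 11 of 15, also when adjusted over the list alone (median -1.54, camera adjusted p = 4.29e-08, adjusted p = 0.0664 with an estimated correlation), with Zg16, a mucus protein, from 5134 ± 699 to 896 ± 236 FPKM and Atoh1, the secretory lineage factor, from 44.7 and 49.8 FPKM in the Control libraries to 14.4 ± 0.0701. Enteroendocrine genes fell in 10 of 15 (12 when adjusted over the list alone, median -2.05, camera adjusted p = 2.53e-08, adjusted p = 0.145 with an estimated correlation), with Gcg, the glucagon gene, at a log2 change of -3.15 ± 0.18. Absorptive colonocyte genes fell in 11 of 23 (13 when adjusted over the list alone, median -1.34, camera adjusted p = 1.23e-05, adjusted p = 0.228 with an estimated correlation), with Slc26a3, the chloride exchanger, from 286 ± 12.4 to 18.2 ± 11.8 FPKM. Of 8 tuft cell genes, Trpm5, Gnat3, Pou2f3 and Dclk1 fell and Avil rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0523, and 0.0234 without Model replicate 1).

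Metabolic genes fell as well. Of 28 genes of oxidative phosphorylation, 18 fell and none rose, and 25 fell when adjusted over the list alone (median -0.83, camera adjusted p = 4.41e-11, adjusted p = 0.273 with an estimated correlation), Sdhb going from 301 ± 11.1 to 138 ± 16.6 FPKM. Xenobiotic metabolism fell in 14 of 26 members, among them Ces2c and Sult1a1, and rose in 1, Ces1g (17 and 1 when adjusted over the list alone, median -1.48, camera adjusted p = 1.8e-06, adjusted p = 0.228 with an estimated correlation). Fatty acid oxidation and PPAR target genes fell in 9 of 23 and rose in 1, Acot12 (10 and 2 when adjusted over the list alone, median -0.73, camera adjusted p = 0.00147, adjusted p = 0.228 with an estimated correlation), Ppara itself going from 4.68 ± 0.684 to 0.891 ± 0.0155 FPKM. Cell cycle genes rose in 3 of 30, the replication helicase genes Mcm3, Mcm7 and Mcm4, and in none when adjusted over the list alone (median 0.42, camera adjusted p = 0.00208, adjusted p = 0.64 with an estimated correlation). The mean of that list lay 0.87 above Control in Model replicate 0 and at -0.07 in Model replicate 1. Without Model replicate 0 its median was -0.08 and it did not pass (adjusted p = 0.917), and without Model replicate 1 the median was 0.91. p53 targets and apoptosis genes rose in 4 of 22, Phlda3, Bcl2l1, Bcl2l11 and Bax, also when adjusted over the list alone (median 0.43, camera adjusted p = 0.0148, adjusted p = 0.353 with an estimated correlation).

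Other lists held members that moved both ways and did not pass as lists. In the prostaglandin and leukotriene pathway, 5 of 26 rose, among them Abcc4 and Ptges, and 3 fell, among them Hpgd, the enzyme that degrades prostaglandins, from 159 ± 7.62 to 34.2 ± 2.67 FPKM (7 and 5 when adjusted over the list alone, camera adjusted p = 0.785, the median was -0.12 and the mean 0.0386). Ptgs1 and Ptgs2, the cyclooxygenase genes that aspirin targets, did not pass, at 16.6 ± 2.79 against 10.9 ± 4.17 FPKM and 3.28 ± 2.42 against 6.87 ± 7.16 in Control and Model (adjusted p = 0.168 and 0.703). Nor did Il6 or Nqo1 (adjusted p = 0.497 and 0.781). Of 28 Nrf2 targets, 2 rose, Hmox1 from 3.72 ± 0.647 to 69.9 ± 56.1 FPKM and Gsta3, and 4 fell, Gstm1, Gstm3, Cbr1 and Osgin1 (4 and 5 when adjusted over the list alone, camera adjusted p = 0.733). Pfkfb3 rose and Pfkfb4 fell among 18 hypoxia and glycolysis genes, Cd80 and Cd86 rose among 13 class II antigen presentation genes, and Ier3, Jun and Egr2 rose among 18 immediate early genes, each also when adjusted over the list alone, with camera adjusted p = 0.416, 0.0557 and 0.132. The class II list passed without Control replicate 0 (adjusted p = 0.0193) and without Model replicate 0 (adjusted p = 0.00155). Arntl, a core clock gene, fell from 23.2 ± 1.90 to 9.48 ± 0.869 FPKM as the only 1 of 15 clock genes to pass, over all genes and over the list alone (camera adjusted p = 0.308). None of 22 DNA methylation and histone deacetylase genes and none of 9 colon position genes passed, also when adjusted over the list alone (camera adjusted p = 0.306 and 0.918). The position genes had a median of 0.17 and a mean of -0.08, which differ in sign.

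In all, 2276 of 14061 genes passed in Model against Control, 962 higher and 1314 lower, and 1523 of them differed at least 2-fold. Of 33 lists, 23 passed with camera, 18 with fry and 1 with an estimated correlation. The count fell to 623 without Control replicate 0, 553 without Control replicate 1 and 1078 without Model replicate 1. Without Model replicate 0 more genes were higher than lower, 875 against 761. All Control libraries are named colon and all others tumour, so the tissue name follows the groups.

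ASA against Model asks what the aspirin diet changed. Only 2 features passed, and both are uncertain. Hba-a2, an alpha-globin gene (chromosome 11, 32296492 to 32297310), was at 30.0 and 17.3 FPKM in ASA and at 0.0361 and 0.0358 in Model (log2 change 4.52 ± 0.33, adjusted p = 0.0125). Its near-identical copy Hba-a1 was at 26.4 and 85.4 FPKM in Model, so the authors' model could assign reads to either gene. A transcript without a gene name, NM_010039, was at 14.2 and 6.81 FPKM in the Model libraries and listed at 0 in the other 8 libraries (adjusted p = 0.0173). The next genes did not pass: Ces1g, a carboxylesterase, at 6.53 ± 1.23 FPKM in Model and 18.0 ± 0.390 in ASA, Gcg with a log2 difference of -1.28 ± 0.18, Des at 75.8 ± 10.6 and 15.7 ± 2.60, and Cnn1 at 47.3 ± 0.119 and 9.08 ± 1.99 (adjusted p = 0.239 for Ces1g and 0.243 for the others).

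Smooth muscle genes had lower values in ASA in 19 of 20 members, none passed over all genes, and 10 fell when adjusted over the list alone (median -0.95, camera adjusted p = 1.66e-19, adjusted p = 0.165 with an estimated correlation). Cytokine and chemokine genes lay higher in 22 of 25, with none passing over all genes or over the list alone (median 0.90, camera adjusted p = 2.27e-10, adjusted p = 0.149 with an estimated correlation). Goblet cell genes lay lower in all 15, of which 1 fell when adjusted over the list alone (median -0.53, camera adjusted p = 3.08e-07, adjusted p = 0.149 with an estimated correlation), Tff3 being at 1751 ± 213 FPKM in Model and 867 ± 18.2 in ASA. Enteroendocrine genes lay lower in 13 of 15, of which 4 fell when adjusted over the list alone, and neutrophil genes lay higher in all 12 with none passing (camera adjusted p = 7.98e-07 and 8.7e-07, adjusted p = 0.199 and 0.238 with an estimated correlation). Neither list passed without ASA replicate 1 (adjusted p = 0.507 and 0.318). Their medians were -0.56 and 0.77, and 0.06 and 0.30 without that library. The enteroendocrine median was -0.27 without Model replicate 0, and the neutrophil median 1.26 without ASA replicate 0. The smooth muscle median was -0.62 without Model replicate 1, that of cytokines 0.57 without ASA replicate 0, and that of goblet cells -0.82 without ASA replicate 0 and -0.28 without ASA replicate 1. The Wnt targets, with a median of 0.08, did not pass (camera adjusted p = 0.568), and did without ASA replicate 0 (adjusted p = 0.0179). The fixed genes Ptgs1, Ptgs2, Il6, Tnf, Nos2, Nqo1, Hmox1 and Axin2 did not pass. Tnf was at 4.58 ± 0.760 FPKM in Model and 10.2 ± 4.09 in ASA, and Ptgs2 at 6.87 ± 7.16 and 20.0 ± 18.6 (adjusted p = 1 for both).

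At an unadjusted p below 0.05, limma called 335 genes in ASA against Model, 2.38% of those tested, where 5% are expected by chance. Of 33 lists, 15 passed with camera and none with an estimated correlation or with fry. The gene count was 0 without ASA replicate 0 and 1 without ASA replicate 1, without Model replicate 0 or without Model replicate 1.

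CUR against Model asks the same of curcumin. The 1 feature that passed was again NM_010039 (adjusted p = 0.0346), listed at 0 in CUR. Interferon response genes lay higher in CUR in all 28 members, with none passing over all genes or over the list alone (median 1.11 and 0.67 without CUR replicate 0, camera adjusted p = 4.79e-17, adjusted p = 0.361 with an estimated correlation). Ido1, a tryptophan-degrading enzyme, was at 7.66 ± 2.53 FPKM in Model and 59.4 ± 10.1 in CUR (adjusted p = 0.934), and Igtp, an interferon-induced GTPase, at 16.3 ± 3.62 and 47.4 ± 3.77 (adjusted p = 0.934). Absorptive colonocyte genes lay higher in 20 of 23 with none passing over all genes or over the list alone (median 0.65, camera adjusted p = 1.76e-05, adjusted p = 0.408 with an estimated correlation). That list did not pass without CUR replicate 0 (median 0.27, adjusted p = 0.0703), and its median was 0.42 without Model replicate 1. Aqp8 was at 18.7 ± 15.5 FPKM in Model and 92.2 ± 56.3 in CUR, and Car4 at 41.8 ± 39.5 and 160.3 ± 3.88 (adjusted p = 0.934 for both).

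Stromal genes lay lower in CUR. Smooth muscle genes did so in 19 of 20, of which 7 fell when adjusted over the list alone (median -0.87, camera adjusted p = 4.65e-12, adjusted p = 0.408 with an estimated correlation). All 15 endothelial genes did so, with none passing over all genes or over the list alone. So did 18 of 21 fibroblast genes, of which 1 fell when adjusted over the list alone (endothelial and fibroblast medians -0.67 and -0.47, camera adjusted p = 1.91e-06 and 3.45e-06, adjusted p = 0.408 and 0.535 with an estimated correlation). Neither of these passed without Model replicate 1 (medians -0.15 and -0.06, adjusted p = 0.284 and 0.751), and their medians were -1.27 and -0.85 without Model replicate 0. By smallest p after NM_010039, without passing, came Cd177, a neutrophil antigen that colon epithelium can also make, at 136 ± 14.8 FPKM in Model and 38.5 ± 8.47 in CUR (adjusted p = 0.379), Steap4 at 30.0 ± 4.49 and 9.25 ± 1.07 (adjusted p = 0.39), Pcsk1 at 3.44 ± 0.129 and 0.855 ± 0.0496 (adjusted p = 0.552), and the heat shock genes Hspa1a and Hspa1b. The fixed genes did not pass, with Ptgs2 at 6.87 ± 7.16 FPKM in Model and 23.1 ± 14.6 in CUR, Hmox1 at 69.9 ± 56.1 and 24.8 ± 5.53, and Nqo1 at 18.0 ± 0.517 and 15.1 ± 8.40 (adjusted p = 0.934, 0.934 and 0.941).

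At an unadjusted p below 0.05, limma called 684 genes in CUR against Model, 4.86% of those tested, where 5% are expected by chance. Of 33 lists, 14 passed with camera and none with an estimated correlation or with fry, and 9 passed without CUR replicate 0 and 9 without CUR replicate 1. The gene count was 2 without CUR replicate 0 and 3 without CUR replicate 1.

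ASA+CUR against Model asks what both agents together changed. The 2 features that passed were Hba-a2, at 9.22 and 18.1 FPKM in ASA+CUR, and NM_010039, listed at 0 (adjusted p = 0.0258 for both), with the same uncertainty as above. The next genes did not pass (adjusted p = 0.124 each): Alb, the albumin gene, at 79.6 ± 46.2 FPKM in Model and 2.57 ± 0.201 in ASA+CUR, Xlr3a at 0.375 ± 0.341 and 6.15 ± 0.355, Arhgap40 at 0.666 ± 0.292 and 3.72 ± 0.170, and Trex2, an exonuclease of stratified epithelium, at 0.892 ± 0.267 and 5.07 ± 0.393. Smooth muscle genes lay lower in 17 of 20, of which 7 fell when adjusted over the list alone (median -0.91, camera adjusted p = 2.75e-06, adjusted p = 0.537 with an estimated correlation). Interferon response genes lay lower in 27 of 28, with none passing over all genes or over the list alone (median -0.74, camera adjusted p = 3.68e-06, adjusted p = 0.537 with an estimated correlation). Without ASA+CUR replicate 1 the interferon list did not pass (median -0.33, adjusted p = 0.0572), and its median was -1.29 without ASA+CUR replicate 0.

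T and NK cell genes lay lower in all 16 and mast cell genes in 12 of 13, of which 1 fell when adjusted over the list alone (medians -0.81 and -1.30, camera adjusted p = 4.47e-05 and 0.000331, adjusted p = 0.537 for both with an estimated correlation). The T and NK cell list did not pass without Model replicate 1 (median -0.24, adjusted p = 0.102), and its median was -1.51 without Model replicate 0. Foxp3, the regulatory T cell factor, was at 2.96 ± 2.30 FPKM in Model and 0.609 ± 0.206 in ASA+CUR, and Tpsb2 at 32.4 ± 25.9 and 3.81 ± 0.915 (adjusted p = 0.458 for both). Goblet cell genes lay lower in 13 of 15, of which 2 fell when adjusted over the list alone (median -0.67, camera adjusted p = 0.000716, adjusted p = 0.502 with an estimated correlation), Atoh1 being at 14.4 ± 0.0701 and 5.55 ± 2.23 FPKM (adjusted p = 0.283). Wnt targets lay higher in 18 of 24 with none passing over all genes or over the list alone (median 0.28, camera adjusted p = 0.0281, adjusted p = 0.537 with an estimated correlation). That call ended without Model replicate 0 (adjusted p = 0.0889), Model replicate 1 (0.056) or ASA+CUR replicate 1 (0.655), the median being 0.05 without this last library and 0.42 without ASA+CUR replicate 0. Colon position genes lay higher in 7 of 9 with none passing over all genes or over the list alone (median 1.80, camera adjusted p = 0.033, adjusted p = 0.537 with an estimated correlation). The position call ended without Model replicate 0 (adjusted p = 0.104), Model replicate 1 (0.077, median 1.11) or ASA+CUR replicate 0 (0.0508). Enteric neuron genes were the list that fry called (adjusted p = 0.0464), with a median of -0.18 (camera adjusted p = 0.00658, adjusted p = 0.502 with an estimated correlation). Without Model replicate 0 they did not pass with camera (adjusted p = 0.0889). Among the fixed genes, none of which passed, Nos2 was at 12.1 and 8.76 FPKM in the Model libraries and 3.03 ± 1.30 in ASA+CUR, Axin2 at 67.8 ± 9.28 and 103 ± 11.1, and Ptgs2 at 6.87 ± 7.16 and 31.2 ± 17.2 (adjusted p = 0.422, 0.519 and 0.486).

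At an unadjusted p below 0.05, limma called 1416 genes in ASA+CUR against Model, 10.07% of those tested. Of 33 lists, 18 passed with camera, 1 with fry and none with an estimated correlation, and 11 passed without ASA+CUR replicate 1. The gene count was 0 without ASA+CUR replicate 0 and 1 without ASA+CUR replicate 1, without Model replicate 0 or without Model replicate 1.

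ASA+CUR against each agent alone asks whether the combination differs from that agent at a higher dose. Each comparison mixes the added agent with the lower dose of the other, and the series has no group that parts them. No gene passed in either comparison. Interferon response genes lay lower in ASA+CUR than in ASA in all 28 members, of which 5 fell when adjusted over the list alone (median -1.39, camera adjusted p = 4.09e-25, adjusted p = 0.115 with an estimated correlation), and lower than in CUR in all 28, of which 26 fell when adjusted over the list alone (median -1.98, camera adjusted p = 2.32e-20, adjusted p = 0.27 with an estimated correlation, and 0.0409 with fry). The median against ASA was -0.83 without ASA replicate 1 and -0.82 without ASA+CUR replicate 1. Irgm2, an interferon-induced GTPase (chromosome 11, 58214977 to 58222783), was at 37.9 ± 1.84 FPKM in ASA, 33.8 ± 4.83 in CUR and 13.2 ± 1.75 in ASA+CUR, with log2 differences of -1.46 ± 0.17 from ASA and -1.29 ± 0.17 from CUR that did not pass (adjusted p = 0.277 and 0.279).

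Against ASA, genes of antimicrobial and mucosal defence lay lower in ASA+CUR in 20 of 22, of which 2 fell when adjusted over the list alone (median -1.25, camera adjusted p = 2.01e-09, adjusted p = 0.11 with an estimated correlation). Nox1 and Nos2, which make superoxide and nitric oxide, were at 15.2 ± 0.180 and 20.1 ± 4.85 FPKM in ASA and 6.44 ± 1.67 and 3.03 ± 1.30 in ASA+CUR (adjusted p = 1 for both). Cell cycle genes lay higher in all 30 with none passing over all genes or over the list alone (median 0.33, camera adjusted p = 1.19e-06, adjusted p = 0.562 with an estimated correlation), and that list did not pass without ASA replicate 1 (median 0.11, adjusted p = 0.147) and had a median of 0.67 without ASA replicate 0. Against CUR, absorptive colonocyte genes lay lower in 21 of 23, of which 8 fell when adjusted over the list alone, and goblet cell genes in all 15, of which 6 did (medians -1.05 and -0.92, camera adjusted p = 1.29e-06 and 1.35e-06, adjusted p = 0.384 and 0.27 with an estimated correlation, fry adjusted p = 0.0409 for goblet cells). Matrix metalloproteinases lay higher in 16 of 17, of which 2 rose when adjusted over the list alone (median 0.73, camera adjusted p = 1.87e-05, adjusted p = 0.384 with an estimated correlation), and did not pass without CUR replicate 1 (median 0.47, adjusted p = 0.0627).

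Several immune cell lists lay lower in ASA+CUR than in ASA or CUR, and none of their genes passed over all genes or over the list alone. Neutrophil and macrophage lists did not lie lower than in CUR. Neutrophil list means were 3.01 and 3.35 in the ASA+CUR libraries against 2.53 and 2.77 in CUR. Those of macrophages and dendritic cells were 4.04 and 4.01 against 4.01 and 3.90. T and NK cell genes lay lower in all 16, with medians of -0.67 against ASA and -0.65 against CUR (camera adjusted p = 4.11e-07 and 0.000571, adjusted p = 0.545 and 0.649 with an estimated correlation). Their median against CUR was -0.38 without CUR replicate 0 and -0.97 without CUR replicate 1. Mast cell genes lay lower in 12 of 13 against ASA and in all 13 against CUR (medians -1.04 and -0.88, camera adjusted p = 0.000918 and 0.0358, adjusted p = 0.545 and 0.649 with an estimated correlation). Within ASA and within CUR, their mean was also lower in the library with more Hoxd13, a gene of colon position described below. Against ASA the mast cell call ended without ASA replicate 1 (median -0.11, adjusted p = 0.979), and the median was -1.94 without ASA replicate 0. Against CUR it ended without CUR replicate 1 (adjusted p = 0.234, median -1.34) or ASA+CUR replicate 0 (0.0589), and the median was -0.47 without CUR replicate 0. B and plasma cell genes lay lower in 13 of 14 against CUR (median -0.60, camera adjusted p = 0.0399, adjusted p = 0.677 with an estimated correlation), which ended without CUR replicate 1 (median -0.12, adjusted p = 0.855) or ASA+CUR replicate 0 (median -0.38, adjusted p = 0.216), and the median was -0.96 without CUR replicate 0.

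Against ASA, neutrophil genes lay lower in 10 of 12, macrophage and dendritic cell genes in 17 of 20, and cytokines and chemokines in 21 of 25, with none passing over all genes or over the list alone. Their medians were -0.53, -0.39 and -0.49 (camera adjusted p = 0.00396, 0.0038 and 7.3e-05, and adjusted p = 0.545, 0.573 and 0.216 with an estimated correlation). S100a8 and S100a9 are in both the neutrophil and the antimicrobial list. The neutrophil call ended without ASA replicate 1 (median -0.07, adjusted p = 0.979) or ASA+CUR replicate 0 (median -0.10, adjusted p = 0.325), and the macrophage call without ASA replicate 1 (median 0.12, adjusted p = 0.461). Without ASA replicate 0 these 2 medians were -1.20 and -0.90. The cytokine call ended without ASA replicate 0 (adjusted p = 0.205) or ASA+CUR replicate 0 (median -0.26, adjusted p = 0.0794), and the median was -0.74 without ASA replicate 1 and -0.82 without ASA+CUR replicate 1.

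At an unadjusted p below 0.05, limma called 399 genes against ASA and 1944 against CUR, 2.84% and 13.8% of those tested, where 5% are expected by chance. The smallest adjusted p was 0.277 against ASA and 0.0516 against CUR, for Hba-a2. Of 33 lists, 20 and 13 passed with camera, none with an estimated correlation, and 0 and 2 with fry. Against ASA, 1 gene passed without ASA+CUR replicate 0, and 11 lists passed without ASA replicate 1. Against CUR, 1 gene passed without ASA+CUR replicate 1 and 1956 without CUR replicate 1. CUR then rests on replicate 0 alone, whose spread is taken from the other groups. That library had low Hoxd13, a gene of colon position described below, and both ASA+CUR libraries had high Hoxd13. Position and treatment cannot be told apart in that fit. With log2 Hoxd13 as a covariate, 12 lists passed against ASA.

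**Figure D3:**
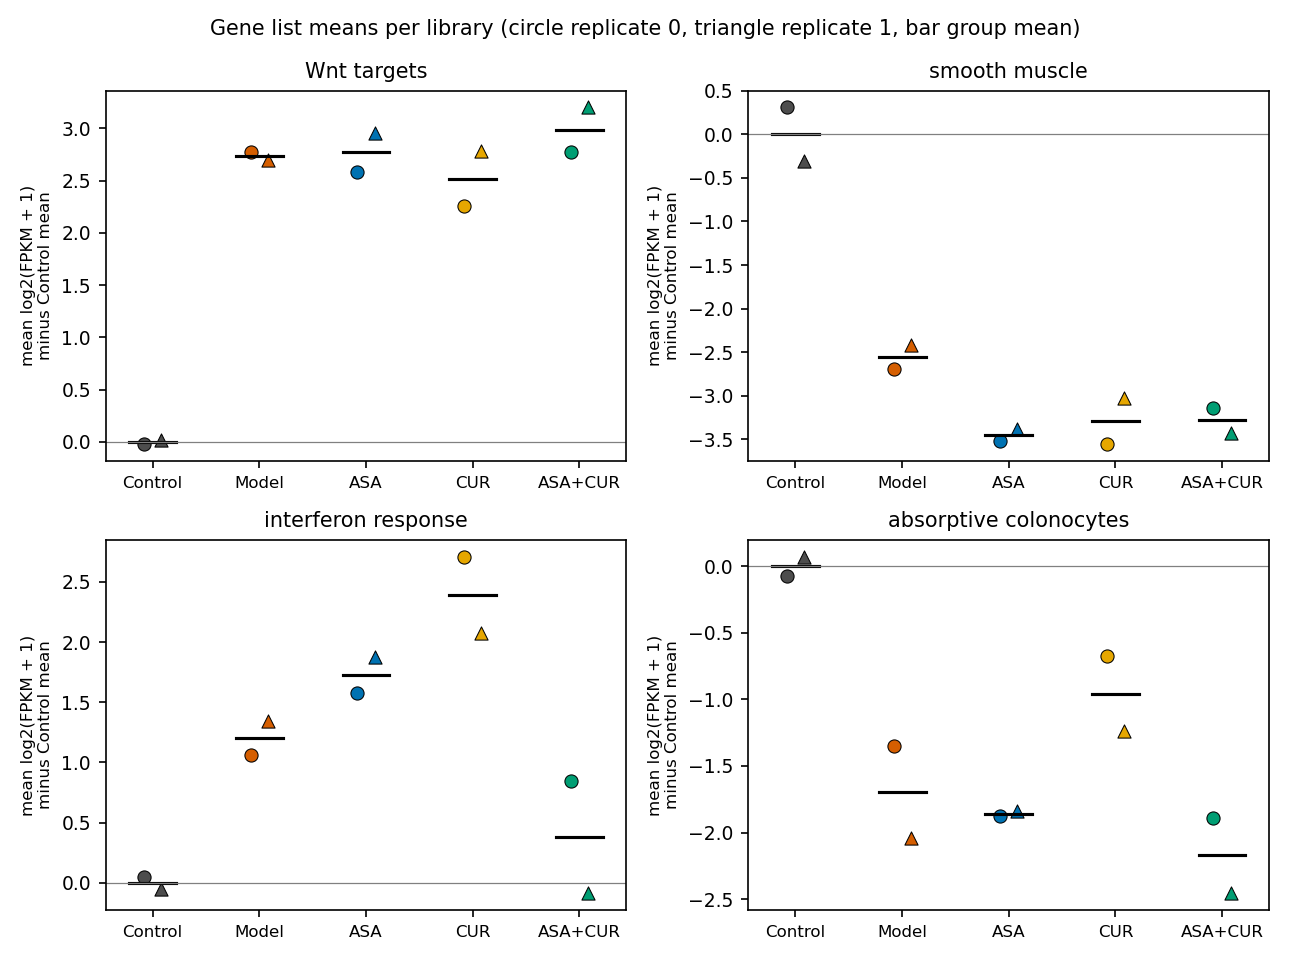
Mean log2(FPKM + 1) of 4 gene lists per library, minus the Control mean (y axis), by group (x axis), with circles for replicate 0, triangles for replicate 1 and bars at group means. Wnt targets lie at 2.26 to 3.20 in the 8 AOM/DSS libraries, and interferon response genes at 2.07 and 2.71 in CUR and at -0.09 and 0.85 in ASA+CUR.

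Whether treatment moved the Model changes back toward Control was read from the 2276 genes that passed there. The 1 gene that passed toward Control in each treated group was NM_010039, and none passed away from it. Over these genes the median log2 shift toward Control was -0.12 in ASA, 0.06 in CUR and -0.16 in ASA+CUR, a negative value lying away from Control. Simulated groups set equal to Model, with all libraries redrawn, gave 0.07 in each case, between 0.05 and 0.08 in 100 sets. Genes were drawn independently, so this range leaves out shifts that many genes of a library share and is too narrow to judge the observed values. Without Model replicate 0 the shift was 0.06 in ASA, 0.05 in ASA+CUR and 0.30 in CUR, and in CUR it was -0.02 without Control replicate 0 and -0.09 without Control replicate 1, so its direction turned with single libraries. In ASA it was -0.21 without Control replicate 0, -0.23 without Control replicate 1, -0.23 without ASA replicate 0 and -0.03 without ASA replicate 1. In ASA+CUR it was -0.28 without Control replicate 1, -0.30 without ASA+CUR replicate 0 and -0.10 without ASA+CUR replicate 1. The single gene was no longer called without either Control library in any group, without either ASA library in ASA, without CUR replicate 0 in CUR, and without either ASA+CUR library in ASA+CUR.

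Against Control, 3163 genes passed in ASA, 2110 in CUR and 4148 in ASA+CUR. Without Control replicate 0 the counts were 1171, 711 and 1702, and without Control replicate 1 they were 1133, 698 and 1736. They were 1632 in ASA without ASA replicate 1, 2312 in ASA+CUR without ASA+CUR replicate 0, and 1481 without ASA+CUR replicate 1. Of the genes called in Model, 2116, 1615 and 2048 were called in the same direction in these groups, against 261, 174 and 341 for independent lists. The simulated sets held at most 1, but Model too was set equal to Control in them, so almost no gene could be called. Neither the simulated sets nor the independent lists give the overlap that shared Control libraries cause when Model differs. All these groups also received AOM and DSS, so an excess over both numbers was fixed by the design.

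The treated groups were also compared with each other through their differences from Model. Across genes, the differences of ASA and ASA+CUR correlated at 0.716 (simulated 0.499 for unchanged groups in all 3 pairs), with a covariance of 0.118 against a simulated 0.0515. For ASA and CUR the correlation was 0.437 and the covariance 0.0558 against 0.0514, and for CUR and ASA+CUR 0.354 and 0.0669 against 0.0513. The Model libraries could not be split into parts of at least 2, so part of any excess may come from those shared libraries. Genes were simulated independently, so the simulated values leave out shifts that many genes of a library share. ASA replicate 0 and both ASA+CUR libraries also had high Hoxd13, a gene of colon position described below, and neither Model library did. The excess for ASA and ASA+CUR therefore cannot be read as an effect of aspirin.

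Genes that mark position along the colon differed between replicates of the same group. Hoxd13, a homeobox gene expressed toward the tail end, was at 75.7 and 0.0566 FPKM in ASA replicates 0 and 1, at 0.0323 and 71.6 in CUR replicates 0 and 1, at 87.7 and 65.2 in ASA+CUR, at 8.35 and 0.0850 in Model, and at 3.52 and 1.86 in Control. Hoxa11 went the other way, at 3.18 and 15.3 FPKM in ASA, 19.6 and 3.23 in CUR, and 3.21 and 3.64 in ASA+CUR. Cdx2, an intestinal identity factor, was at 5.22 and 61.1 FPKM in ASA, 126 and 11.4 in CUR, 6.34 and 7.05 in ASA+CUR, 64.1 and 62.8 in Model, and 139 and 124 in Control. Krt5, a keratin of squamous epithelium, was at 94.5 FPKM in ASA replicate 0, 212 in ASA+CUR replicate 0 and 10.3 in Model replicate 0, and at most 0.161 in the other 7 libraries. Without ASA replicate 0 and ASA+CUR replicate 0, 1581 genes passed in Model against Control, 1 in ASA+CUR against Model and 0 in CUR against Model. Both ASA+CUR libraries, in which the interferon, goblet cell and colonocyte lists lay lower than in CUR, had high Hoxd13, as did 1 of 2 libraries in ASA and in CUR and neither in Model. Mast cell list means were 1.76 and 3.53 in ASA replicates 0 and 1, and 3.06 and 2.38 in CUR replicates 0 and 1. In both groups the library with high Hoxd13 had the lower mean, a difference that rests on single libraries. The means were 1.82 and 1.64 in ASA+CUR. Position and treatment cannot be told apart for the lower mast cell genes in ASA+CUR.

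**Figure D4:**
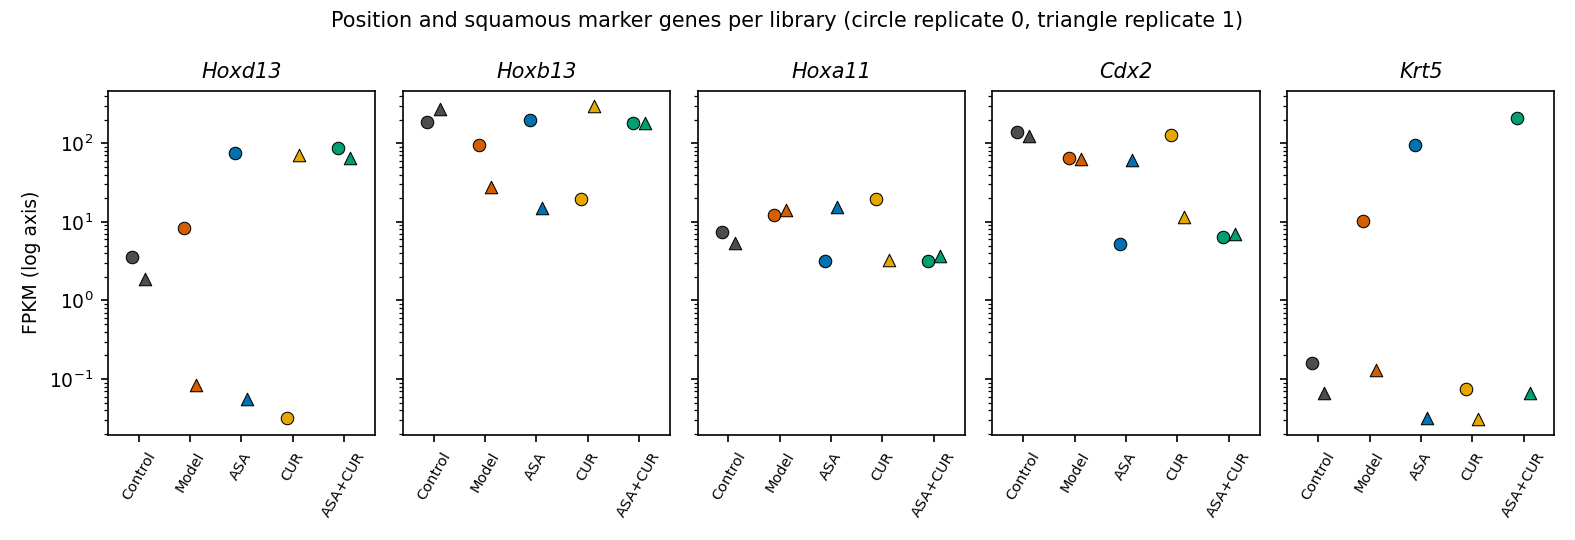
FPKM on a log axis (y) of Hoxd13, Hoxb13, Hoxa11, Cdx2 and Krt5 in each library, by group (x), with circles for replicate 0 and triangles for replicate 1. Hoxd13 reaches 65.2 FPKM or more in ASA replicate 0, CUR replicate 1 and both ASA+CUR libraries, and stays at 8.35 or below in the other 6 libraries.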

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

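The fits with log2 Hoxd13 as a covariate, without small RNA features and without the 2 libraries with the most Krt5 were chosen only after results had been seen. So were all comparisons of a treated group with Control and the list tests of ASA+CUR against ASA and against CUR. The other tests in this part were planned. Named results past the threshold, 479 in number, were refitted 8568 times, of which 7741 kept their call in the same direction, 827 lost it and 0 turned direction. Many of these settings differ little from the main fit. In the fits that left out 1 library, 1386 kept their call and 530 lost it. The share of called genes higher in Model than in Control was 42.3%, against 49.6% with a pseudocount of 0.1, 33.6% with a pseudocount of 5, 34.2% with no filter, and 41.9% and 40.8% with the scalings. Leaving out 1 library gave 34.9% to 53.5%, and the balance turned without Model replicate 0, at 53.5%. Median-of-ratios scaling and robust empirical Bayes moved none of the counts of genes and lists by over 1.5 times. Where a count moved, the cause was not tested. How many reads each library had is not given, so depth was not corrected for.

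The small counts of the treated groups moved with most settings. With a pseudocount of 0.1, CUR against Model gave 0 genes, ASA+CUR against CUR 1, and the reversal in CUR 0. With a pseudocount of 5, ASA, CUR and ASA+CUR against Model gave 0 each, and so did the 3 reversals. With no filter on low values, CUR against Model gave 0, ASA+CUR against ASA 2 and the reversal in CUR 0. With a filter of 5 FPKM, ASA against Model gave 1, CUR 0 and ASA+CUR 0, and the 3 reversals gave 0 each. With each transcript tested, the 3 comparisons with Model and the 3 reversals gave 0 each. With quantile normalization, CUR against Model and the reversal in CUR gave 0 each. With no intensity trend, ASA+CUR against CUR gave 1. Without small RNA features, ASA+CUR against CUR gave 1.

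With only the groups compared in the fit, ASA against Model gave 0 genes, CUR 0 and ASA+CUR 4, and ASA+CUR gave 1 against ASA and 1 against CUR. Against Control, CUR then gave 1395 and ASA+CUR 6758, and the reversals in ASA, CUR and ASA+CUR gave 0, 0 and 19. With the Hoxd13 covariate, CUR against Model and ASA+CUR against Model gave 0 each, the reversals in CUR and ASA+CUR 0 each, and 12 lists passed in ASA+CUR against ASA. Without the 2 libraries with the most Krt5, CUR against Model gave 0 and ASA+CUR against Model 1, ASA+CUR gave 1 against ASA and 1 against CUR, ASA against Control 1550 and ASA+CUR against Control 2061, and the 3 reversals 0 each.

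With an estimated correlation, 1 list passed in Model against Control and 0 in ASA, CUR and ASA+CUR against Model and in ASA+CUR against ASA and against CUR. With fry, 0 lists passed in ASA against Model, 0 in CUR against Model, 1 in ASA+CUR against Model, 0 against ASA and 2 against CUR.

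With a replicate block, 2062 genes passed in Model against Control, 2 in ASA, 0 in CUR and 0 in ASA+CUR against Model, and 0 in ASA+CUR against ASA and against CUR. The reversals in CUR and ASA+CUR gave 0 each. Lists numbered 23, 16, 17, 17, 20 and 13 in the 6 comparisons in that order under the block. The samples share only a replicate number, and the deviations of same-numbered libraries from their group means correlated between -0.214 and 0.326.

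Leaving out 1 library gave 553 to 1636 genes in Model against Control, 0 to 1 in ASA, 1 to 3 in CUR and 0 to 1 in ASA+CUR against Model, and 0 to 1 in ASA+CUR against ASA. In ASA+CUR against CUR it gave 0 to 1956, the highest without CUR replicate 1. Against Control it gave 1133 to 2174 in ASA, 698 to 3060 in CUR and 1481 to 2312 in ASA+CUR, and each reversal gave 0 to 1. Lists numbered 22 to 25 in Model against Control, 15 to 19 in ASA, 9 to 16 in CUR and 11 to 23 in ASA+CUR against Model, 11 to 17 against ASA and 9 to 17 against CUR.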

Other observations

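The tests of treated groups against Control and of the muscle wall, the immune cells, the combined treatment and the position correlation were chosen only after the result was seen. The limits of the squamous epithelium test and of the interferon test with Hoxd13 were written before their results, and how their spread was to be read, with intervals over libraries for list means, was settled after.

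Against Control, Wnt targets rose in 20 of 24 members in ASA, 19 in CUR and 22 in ASA+CUR, and in 23, 20 and 23 when adjusted over the list alone. Their medians were 2.39, 2.21 and 2.54 (camera adjusted p = 1.64e-15, 3.7e-16 and 9.23e-15, and adjusted p = 0.0566, 0.0913 and 0.0794 with an estimated correlation). Axin2 was at 71.3 ± 8.86 FPKM in ASA, 68.9 ± 35.1 in CUR and 103 ± 11.1 in ASA+CUR, against 13.5 ± 0.605 in Control (SD, n = 2, adjusted p = 0.00213, 0.00367 and 0.000763). Enteric neuron and glia genes fell in 14 of 15 members in each treated group, over all genes and over the list alone. The medians were -1.94, -2.26 and -2.19 (camera adjusted p = 3.71e-12, 3.23e-15 and 1.37e-11), and the calls held with an estimated correlation (adjusted p = 0.0307, 0.0179 and 0.0344).

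Of 28 interferon response genes, 14 rose in ASA, 17 in CUR and 2 in ASA+CUR against Control, and 21, 26 and 0 did when adjusted over the list alone (medians 1.82, 2.23 and 0.35). The list passed in ASA and CUR (camera adjusted p = 6.48e-08 and 1.14e-13, adjusted p = 0.203 and 0.128 with an estimated correlation) and did not in ASA+CUR (camera adjusted p = 0.196), where it did without ASA+CUR replicate 1 (adjusted p = 0.000772). ASA and CUR were not compared with each other. Between ASA+CUR and ASA or CUR the list passed with camera and was lost with an estimated correlation (adjusted p = 0.115 and 0.27 with an estimated correlation). Usp18 was at 25.4 ± 22.0 FPKM in ASA, 37.0 ± 6.15 in CUR and 9.84 ± 1.66 in ASA+CUR, against 1.45 ± 0.259 in Control (SD, n = 2, adjusted p = 0.00552, 0.0027 and 0.0188).

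The first pattern weighed is that the ASA+CUR and Model libraries differ along the axis that splits the libraries within ASA and within CUR. The replicate differences in ASA and CUR, taken as the library with more Hoxd13 minus the other, correlated with ASA+CUR minus Model at 0.536 and 0.374 over 14038 genes without Hox genes. These values, which replaced an average over both pairs after its higher result was seen, describe the axis and do not test colon position of the sampled piece as its source. Without the 2 libraries with the most Krt5, CUR replicate 1 minus 0 correlated with ASA+CUR replicate 1 minus Model at 0.325, and at 0.289 and 0.299 against Model replicates 0 and 1 alone (lower bootstrap bound of the lowest 0.252). Of the limits written beforehand, squamous epithelium as the source required a value below 0.1, which was exceeded. The limit of 0.3 against it was not cleared by more than the spread. The bootstrap is over genes and the differences rest on single libraries, so squamous epithelium stays open. Position, squamous epithelium and the combined treatment cannot be told apart for these libraries, since the lowest Hoxd13 value in ASA+CUR was 7.82 times the highest in Model and no library matched across the groups.

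For the lower interferon response genes in ASA+CUR than in CUR, fewer T, NK and myeloid cells would lower their markers as far, if those cells held the interferon transcripts. The T and NK cell list did lie lower (camera adjusted p = 0.000571), a call lost with an estimated correlation, and the markers had a median of -0.38. The interferon median minus that of the markers was -1.60 (95% bootstrap interval over genes -1.97 to -1.23). Over libraries the difference of list means was -1.74 (95% interval -2.78 to -0.71). This argues against a loss of transcripts held by such cells as the whole cause. T and NK cell genes were low, where the log2 scale understates a change. Whether such cells act on the interferon genes of other cells was not tested. With log2 Hoxd13 as a covariate the median difference was -1.70, against -1.98 without it. Under the limits written beforehand, a strong shrinkage would speak for position, and a median that kept most of its size against it. The value met the limit against position, but that limit took no account of the spread between libraries. An interval over libraries was added after the result was seen. The adjusted list mean was -1.79, with a 95% interval over libraries of -2.89 to -0.69. This interval leaves out 0, but it holds both a small and a large share of the unadjusted mean of -2.01. Hoxd13 is also only a stand-in for position, so whether position is the whole cause stays undecided. Against ASA the median went from -1.39 to -0.86. The adjusted list mean was -1.13 (95% interval -2.22 to -0.03), so the shares of position and of the treatment cannot be told apart. Nor can the added agent be told apart from the lower dose of the other, since ASA+CUR held 0.01% ASA with 1% CUR. Within groups, libraries with more Hoxd13 had interferon medians of -0.54 in ASA (18 of 28 genes lower) and -0.35 in CUR (19 of 28) relative to the other, and between groups medians were -1.12 and -2.14 for ASA+CUR replicates 0 and 1 minus CUR replicate 1, with 28 of 28 genes lower in each.

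The third pattern is the fall of muscle and nerve genes and the rise of Wnt targets in Model. Pieces with less muscle wall would lower smooth muscle and enteric neuron genes alike, and their medians differed by -0.50 (95% bootstrap interval over genes -1.36 to 0.29, and -1.30 to 0.24 for list means over libraries). These wide intervals hold unlike falls as well. Enteric neuron genes were also low in Model, where the log2 scale understates a change. A loss of the wall from the pieces stays possible as a source of that fall and was not shown. Such a loss would raise all other transcripts alike. Wnt targets lay 3.57 above absorptive colonocyte genes (95% bootstrap interval over genes 2.24 to 5.51, and 3.10 to 5.76 for list means over libraries). Colonocyte genes fell themselves, so that difference does not give the size of such a rise. The median change over all tested genes was 0.017, while the mean of the Wnt targets lay 2.77 and 2.69 above Control in the Model libraries. This argues against a rise shared by all other transcripts as the source for the Wnt targets. Whether AOM and DSS acted on muscle and nerves or the pieces were taken to another depth was not tested.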
